A study of Homo sapiens with 7 samples.

How the data were processed

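ATAC-STARR-seq was performed in GM12878 cells, with 3 reporter RNA libraries, 3 reisolated plasmid DNA libraries and 1 input plasmid library. Groups were taken from the sample titles. The submitters' processing notes name hg38, Trim Galore, Bowtie2 and Genrich, with neither versions nor roles. The files were 1 accessible peak list and 4 lists of active and silent bins and regions, each made for the series as a whole. Which libraries entered each list, the counting tool, the test and its threshold were not given in the sources used here.

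In the peak list as deposited, each peak carried a signal value, which is never negative and grows with peak length. It also carried −log10 q-values from the authors' peak caller, the lowest −log10 q being 4.00. In the deposited bin and region lists, each entry carried a signed score, called the activity value here, above 0 in every active entry and below 0 in every silent one. It reads as a log-scale ratio of reporter RNA to plasmid DNA, but its base and scaling were not given in the sources used here. These values are the authors' and were used only to describe and rank entries within a list. The bin identifiers number windows of 50 bp every 10 bp from the start of each peak, 6709222 in all, and 100% of called bins lay at the position their number gives. Each region equalled the merge of touching or overlapping bins of its kind, with the mean of their values (tolerance 1e-05) in 100% of regions. No region reached a second peak. No columns of per-sample values were used, so neither the depth per library nor the spread between replicates could be had, and calls in weak peaks rest on an unknown number of reads.

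Gene positions came from an NCBI RefSeq gene table of the assembly GRCh38.p14, whose chromosomes are those of hg38. The table used here has neither strand nor exons, and no genome sequence was used. The tests fixed in advance were written for transcription start sites. They were run instead on windows of 1 kb either side of both annotated ends of each of 19974 protein-coding genes, so a window can belong to several neighbouring genes. Base composition and motif content were fixed as results in advance and were not analysed here. Peaks and regions were placed by their midpoints, and coordinates are 1-based. Comparisons used chromosomes 1 to 22 and X.

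Intervals of shares, odds ratios and differences of medians are 95% percentile intervals from 1000 bootstrap resamples of 5 Mb genome blocks. Sign-flip permutation tests over 23 chromosomes were two-sided, with 100000 resamples. For the odds ratio of a gene-end position, 0.5 was added to each cell of a chromosome's table. Co-occurrence of active and silent calls in peaks was given as a Mantel-Haenszel odds ratio over 10 deciles of peak length. For 19 gene lists of 762 entries, written before the data were examined, genes with a peak in the window were compared with all other such protein-coding genes by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over 38 tests and a threshold of 0.05. Within deciles of peak signal or gene length, lists were tested by the two-sided Cochran-Mantel-Haenszel test, a large-sample approximation, adjusted in the same way. All listed genes were matched, 2 of them through another symbol. Genes were named by a rule fixed in advance: the 12 with an active and no silent region and the 12 with a silent and no active region with the largest absolute bin value in the window, and up to 4 genes per list and kind of call in the same ranking. List members without a call that are named as exceptions were chosen after their values were seen.

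The statistics were tested on simulated data. Over 20 simulated sets of 100000 peaks with a planted odds ratio of 0.4, the mean Mantel-Haenszel estimate was 0.403, and 19 intervals held the planted value. In simulated sets of 10000 genes, 94.5% of lists of 40 genes with a planted odds ratio of 5 were called by Fisher's exact test, and 0.53% of lists with none. The simulated peaks had no likeness within blocks, and the simulated genes no clusters or shared regions. These rates and the share of intervals that held the planted value therefore need not hold in the real data. Alternatives covered the window (500 bp and 2 kb), region width, peak signal, strata, block size and autosomes. Others were added after the data were examined: the more accessible gene end alone, gene length strata, rotations of a list along the gene order, and calls in separate parts of a peak. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.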

Results

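The series measured regulatory activity across accessible chromatin in GM12878, an Epstein-Barr virus-transformed human B lymphoblastoid cell line, by ATAC-STARR-seq. In this assay, DNA fragments from accessible chromatin are cloned into reporter plasmids, the plasmids are placed in cells, and the reporter RNA that the fragments drive is compared with the plasmid DNA recovered from the same cells. The 7 libraries were 3 of reporter RNA, 3 of reisolated plasmid DNA and 1 of the input plasmid library. The files held 1 call set for the whole series: 101904 accessible peaks, and the bins and regions called active (more RNA than DNA) or silent (less RNA than DNA). No values per library were analysed here, so the depth of each library is unknown, and the spread between replicates could not be measured. Intervals and p-values below therefore describe the spread over the genome or over genes, not over replicates.

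Accessible peaks lay mostly away from gene ends. Of the 101896 peaks on chromosomes 1 to 22 and X, 13.7% (95% block bootstrap interval 13 to 14.3) had their midpoint within 1 kb of either annotated end of a protein-coding gene. A further 50.2% (49.2 to 51.1) lay inside a protein-coding gene but farther from its ends, and 36.2% (35.2 to 37.2) lay outside such genes. The peaks had a median width of 457 bp and covered 66.6 Mb of hg38. Peak names ran to number 174084, above the 101904 peaks listed, and whether peaks had been filtered was not given in the sources used here. The gene table used here gave no strand, so the window was set at both ends of each gene and mixes promoters with 3' ends. The share near gene ends was 22.2% among the peaks with a signal above the median.

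The comparison of reporter RNA with reisolated plasmid DNA asks which accessible sequences raise and which lower reporter output. The authors' deposited table held 251895 active bins, merged into 30078 active regions, and 339737 silent bins, merged into 21125 silent regions. Active regions had a median width of 100 bp and covered 3.96 Mb, and silent regions had a median width of 140 bp and covered 4.42 Mb. The longest active region spanned 1010 bp and the longest silent region 1750 bp. An active call fell in 21.1% of peaks and a silent call in 13.7%. Each bin carried a signed activity value whose log base was not given in the sources used here. In the authors' deposited table, the median value was 0.874 for active bins and -1.24 for silent bins. Without regions shorter than 100 bp, 15203 active and 13560 silent regions were left.

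Among genes with an active and no silent region in the window, the largest bin values stood at VPS53, EDNRA and IFIT5. Their largest bin values in the authors' deposited table were 3.38, 3.34 and 3.33. VPS53 encodes a subunit of a complex that tethers vesicles at the Golgi, EDNRA the endothelin receptor type A, and IFIT5 an interferon-induced RNA-binding protein. The region that held the largest bin at IFIT5 lay at chromosome 10, positions 89415545 to 89415614, inside the annotated gene (89414568 to 89420997), and it also fell in the window of LIPA, which encodes lysosomal acid lipase. ZNF629, TWIST1 (a transcription factor of mesoderm), RARA (retinoic acid receptor alpha) and BOLL (a germ cell RNA-binding protein) followed, at 3.23, 3.04, 2.88 and 2.83 in the authors' deposited table. The neighbours ODAD3 and PRKCSH shared the region with their largest bin, on chromosome 19, with a value of 2.68, and so did the neighbours AK9 and FIG4, on chromosome 6, with 2.67, both from the authors' deposited table. Exon and intron positions were not used here. This ranking took no account of peak depth. The median active bin value fell from 1.504 in the lowest decile of peak signal per bp to 0.666 in the highest. Large values can therefore mark weak peaks. VPS53 had only 70 bp of active sequence in its window, below the width setting of 100 bp. The largest active bin value in the authors' deposited table, 5.03, lay outside these windows or at a gene with a silent region.

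Among genes with a silent and no active region, URGCP-MRPS24, a readthrough locus on chromosome 7, had the lowest bin value in the authors' deposited table, -6.56. CBX6, which encodes a Polycomb group protein, followed at -6.16, with the silent region of that bin at chromosome 22, positions 38871988 to 38872137, just inside the edge of the gene (38861422 to 38872216). MIER3 stood at -5.56 and QKI, an RNA-binding protein that shared the region of its lowest bin with a neighbouring uncharacterised locus, at -5.52, both from the authors' deposited table. CDON, ZBTB24, WDTC1, AGPAT2 and GLIPR2 lay between -5.48 and -5.30 in the authors' deposited table. TNFRSF1B, the type 2 receptor of tumour necrosis factor, had -5.24 in the authors' deposited table, with the silent region of that bin at chromosome 1, positions 12167147 to 12167376, just inside the annotated gene (12166991 to 12209220). CAMTA1 closed the list of 12, with -5.24 in the authors' deposited table. Peak depth was not taken into account in this ranking either. The median silent bin value was -1.49 in the lowest decile of peak signal per bp and -1.12 in the highest.

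Silent regions lay close to gene ends more often than active regions did. The midpoint was within 1 kb of a gene end in 55.9% of silent regions (54.9 to 56.9) and in 28.7% of active regions (27.4 to 30.0), against 5.68% of the peaks with no call. The odds ratio, active against silent, was 0.317 (95% block bootstrap interval 0.296 to 0.34). It was below 1 on 23 of 23 chromosomes, from 0.201 to 0.568, and the two-sided sign-flip permutation test over chromosomes gave p = 1e-05, the smallest that 100000 resamples can give. Within 200 bp of a gene end, 23.5% of bins were silent and 9.03% active, whereas beyond 10 kb the order was the opposite, with 1.68% silent and 3.45% active. These shares of bins took no account of peak depth. The order also turned with depth: 0.113% of bins were silent and 1.18% active in the lowest decile of peak signal per bp. In the highest decile they were 13.4% and 7.43%. Of the peaks in these deciles, 7.97% and 51.8% lay near a gene end. For regions, the odds ratio over deciles of signal per bp and length was 0.344. Distal active regions (28.8% outside genes and 42.5% inside genes) also carried larger values than those near gene ends, with medians of 1.06 and 0.785 in the authors' deposited table. Within deciles of peak signal per bp, the mean of that difference, gene end minus other, was -0.00894, against -0.277 over all. By decile it ran from -0.0688 to 0.0552, so the difference was nearly absent between peaks of like signal.

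**Figure D1:**
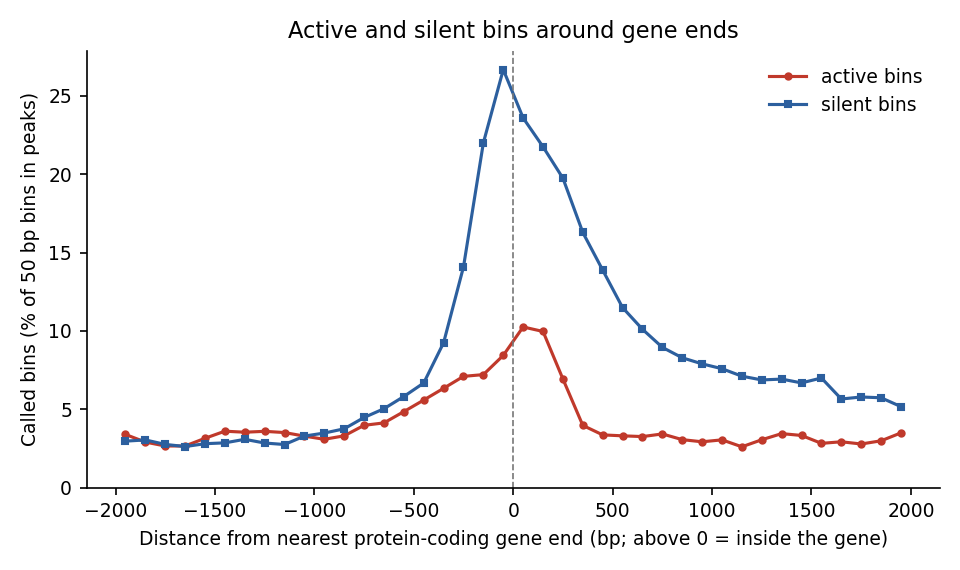
Percentage of the 50 bp bins in accessible peaks that were called active (red circles) or silent (blue squares), in 100 bp steps of distance from the nearest end of a protein-coding gene; values above 0 lie inside the gene. Silent bins reached 26.7% in the last 100 bp outside the gene, and active bins reached 10.3% in the first 100 bp inside it. Peak depth was not taken into account.

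Active and silent calls shared a peak less often than peaks of like length would give. Of the 101896 peaks, 17101 held active calls only, 9561 silent calls only, 4433 both and 70801 neither. Longer peaks held more calls of either kind, so the odds ratio for sharing a peak was taken over 10 deciles of peak length. It was 0.38 (95% block bootstrap interval 0.358 to 0.4) and below 1 on 23 of 23 chromosomes (two-sided sign-flip permutation test, p = 1e-05, the smallest possible). A bin holds at most 1 call, so some or all of this may be built in. For calls on opposite sides of the peak midpoint the odds ratio was 0.525. At opposite ends of peaks of at least 2 kb it was 0.8003. In the longest decile, 3174 peaks held both calls where independence would have given 3668. With no account of length the direction turned, to an odds ratio of 1.92 (two-sided Fisher's exact test, p = 1.5e-218). In the 4433 peaks with both kinds, active bins lay farther from the peak summit than silent bins, by a median of 176 bp (160 to 188), and they did so in 65.3% of these peaks. Depth along the peak was not taken into account in this distance.

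**Figure D2:**
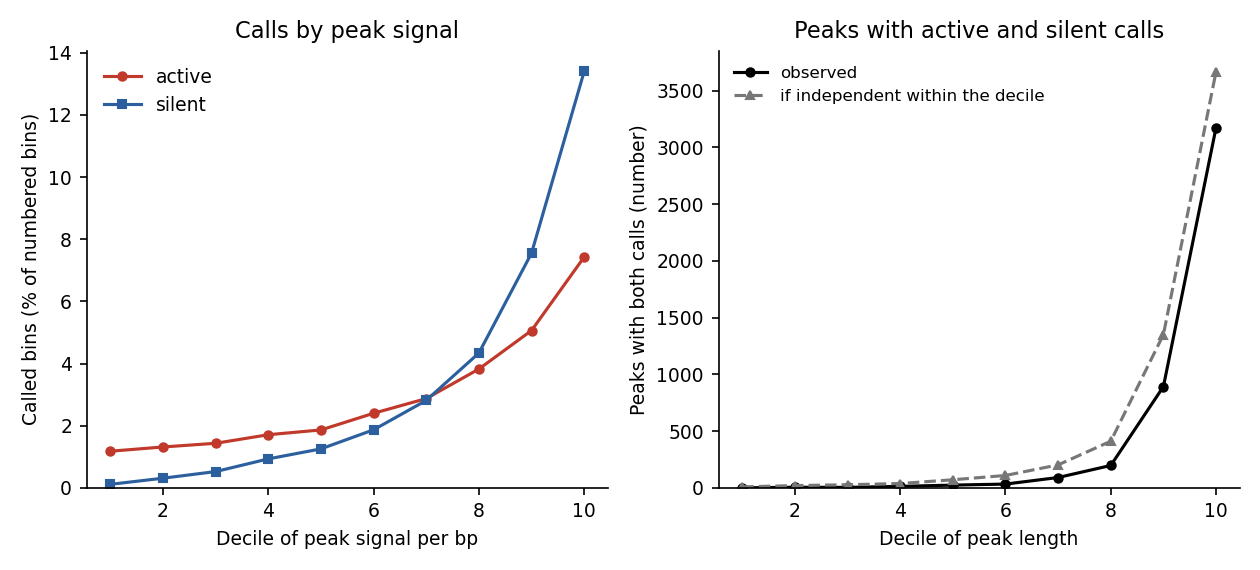
Left, percentage of numbered bins called active (red circles) or silent (blue squares) in each decile of peak signal per bp. Right, number of peaks that held both calls in each decile of peak length (black circles) and the number that independence within the decile would give (grey triangles). Called shares rose from 1.18% to 7.43% for active bins and from 0.113% to 13.4% for silent bins, and the observed number lay below the independent one in all 10 length deciles.

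Gene lists fixed before the data were examined differed widely in the calls at their gene ends. Of 19974 protein-coding genes, 13686 had a peak in the window at 1 end or both. Among these, 49.0% had an active region there, 59.2% a silent region and 26.5% both. Over 19 lists and both kinds of call, two-sided Fisher's exact tests with Benjamini-Hochberg adjustment gave 7 lists with more active genes, 2 with fewer active genes, 2 with more silent genes and 10 with fewer silent genes than the other accessible genes. With genes compared within deciles of their peak signal, these numbers were 5, 0, 0 and 6.

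Replication-dependent histone genes, which supply histones in S phase, and interferon-stimulated genes stood at the top for active calls. An active region was present at 50 of 51 accessible histone genes (98.0%; Fisher's exact test, adjusted p = 3.36e-13), all but H3C6, and a silent region at 5 (9.80%; Fisher's exact test, adjusted p = 3.86e-12). H4C6 had the largest value of the list, 2.62 in the authors' deposited table, from a region at chromosome 6, positions 26240020 to 26240119, beside the gene (26240393 to 26240793). H2AC17 and H2BC17 shared a region with a largest bin value of 2.0, and H2AC13 had 1.66, both from the authors' deposited table. Fisher's exact test counted genes that share a region as separate genes. Of the 37 accessible interferon-stimulated genes, 36 had an active region (97.3%; Fisher's exact test, adjusted p = 1.36e-09), all but SAMD9, and 13 had a silent region (35.1%; Fisher's exact test, adjusted p = 0.0105). After IFIT5, the largest values were at XAF1, IFIT2 and MX2, with 2.08, 2.08 and 2.02 in the authors' deposited table. IRF1, RSAD2, OAS3 and EIF2AK2 held silent as well as active regions.

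Genes of the protein synthesis, respiration and protein turnover machinery also had active regions more often than other genes. These were 65 of 75 ribosomal protein genes (86.7%; Fisher's exact test, adjusted p = 1.12e-10), 57 of 68 oxidative phosphorylation genes (83.8%; Fisher's exact test, adjusted p = 2.09e-08) and 25 of 32 proteasome genes (78.1%; Fisher's exact test, adjusted p = 0.0035). Silent regions were less frequent than in other genes at the ribosomal protein genes (36.0%; Fisher's exact test, adjusted p = 0.000336) and the oxidative phosphorylation genes (35.3%; Fisher's exact test, adjusted p = 0.000358). RPL24, RPL12 and RPL35A had the largest active values among ribosomal protein genes, 2.43, 2.31 and 2.0 in the authors' deposited table, with no silent region in their windows. ATP5PO and NDUFB5, subunits of ATP synthase and of complex I, had 2.39 and 2.14 in the authors' deposited table. RPL6, RPS19 and RPLP2 had both kinds of region. Active regions were present at 25 of 35 mitotic genes (71.4%; Fisher's exact test, adjusted p = 0.0203), such as CCNB2 and BUB1B, and at 22 of 30 genes of the unfolded protein response (73.3%; Fisher's exact test, adjusted p = 0.02), such as XBP1 and ATF6. The mitotic call did not pass with windows of 500 bp (odds ratio 2.08, main 2.61) or within deciles of peak signal (2.01). The unfolded protein response call did not pass with windows of 500 bp (odds ratio 2.08, main 2.87), with regions of at least 100 bp (2.28) or within deciles of peak signal (1.84).

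Immediate-early genes, which respond within minutes to growth signals, and cholesterol biosynthesis genes had silent regions more often than other genes. A silent region was present at 27 of 29 immediate-early genes (93.1%; Fisher's exact test, adjusted p = 0.000336), all but JUN and PPP1R15A. JUND had silent regions at chromosome 19, positions 18279581 to 18279780, 18280211 to 18280520 and 18281101 to 18282100, within or beside the gene (18279694 to 18281622), and active regions at 18278901 to 18278980, which held its largest active bin, and at 18279321 to 18279530. FOSL2 and KLF6 had silent regions and no active region. Of 27 cholesterol biosynthesis genes, 25 had a silent region (92.6%; Fisher's exact test, adjusted p = 0.000806), among them INSIG1, DHCR7, MVK and MVD, and the exceptions were CYP51A1 and HMGCS1. Within deciles of peak signal, the adjusted p was 0.191 for each of these 2 lists (odds ratios 3.71, main 9.33, and 3.67, main 8.63), and the cholesterol call did not pass with windows of 500 bp either (odds ratio 2.64). Active regions at immediate-early genes did not pass in the 1 kb window (17 of 29, Fisher's exact test, adjusted p = 0.396) and passed with 2 kb (Fisher's exact test, adjusted p = 0.0463). Their odds ratio turned to 0.739 within deciles of peak signal (main 1.48), and it was also below 1 at the more accessible gene end alone.

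**Figure D3:**
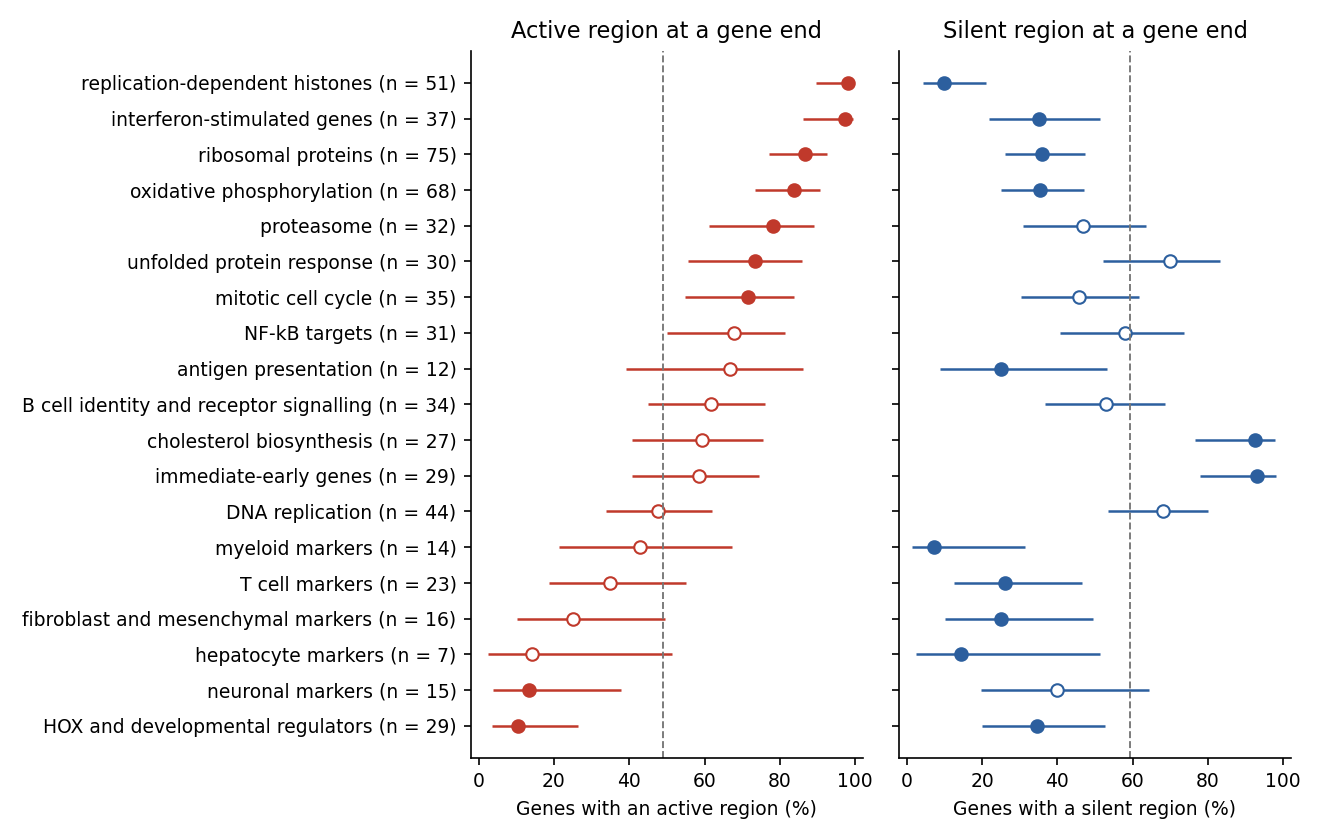
Percentage of the accessible genes of each list with an active region (left, red) or a silent region (right, blue) within 1 kb of a gene end, with 95% Wilson intervals that cover counting error only. Filled points passed an adjusted p of 0.05 and dashed lines mark all accessible genes, at 49.0% and 59.2%; histone and interferon-stimulated genes lie at the top for active regions, and immediate-early and cholesterol biosynthesis genes at the far right for silent regions.

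B cell and NF-kB lists did not pass the test for either kind of call in the 1 kb window, and both passed for more active genes with the 2 kb window (Fisher's exact test, adjusted p = 0.0133 and 0.0355). Active regions were present at 21 of 34 genes of B cell identity and receptor signalling (61.8%; Fisher's exact test, adjusted p = 0.247), with the largest values at SWAP70, FCRLA and FCER2. They were present at 21 of 31 NF-kB targets (67.7%; Fisher's exact test, adjusted p = 0.0806), with BIRC3, an inhibitor of apoptosis, first at 1.99 in the authors' deposited table. Among NF-kB targets with a silent region, NFKBIE, an inhibitor of NF-kB, ranked first. The region with its lowest bin, at chromosome 6, positions 44257207 to 44257746, lay inside the neighbouring gene SLC35B2 (44254101 to 44257890), and another silent region at 44265096 to 44265765 spanned the other end of NFKBIE (44258166 to 44265551). DNA replication genes had an active region in 47.7% and a silent region in 68.2% of 44 genes and passed neither test (Fisher's exact test, adjusted p = 0.905 and 0.335). Of 30 listed antigen presentation genes, only 12 had a peak in the window. A silent region was present at 3 of these 12, CIITA, RFXAP and IFI30 (25%, Fisher's exact test, adjusted p = 0.0369). This last call did not pass with windows of 500 bp, with regions of at least 100 bp, at the more accessible gene end alone or within deciles of gene length, where the odds ratios were 0.25, 0.305, 0.251 and 0.242 (main 0.229).

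Some lists of markers of other cell types had fewer calls than other accessible genes. Active regions were present at 3 of 29 HOX and developmental regulators (10.3%; Fisher's exact test, adjusted p = 0.000105), namely HOXB6, HOXB5 and DLX1, and at 2 of 15 neuronal markers (13.3%; Fisher's exact test, adjusted p = 0.0187), namely NEUROG2 and ELAVL3. Silent regions were less frequent at T cell markers (6 of 23; Fisher's exact test, adjusted p = 0.00617), myeloid markers (1 of 14; Fisher's exact test, adjusted p = 0.000336), fibroblast and mesenchymal markers (4 of 16; Fisher's exact test, adjusted p = 0.0193), hepatocyte markers (1 of 7; Fisher's exact test, adjusted p = 0.0379) and HOX and developmental regulators (10 of 29; Fisher's exact test, adjusted p = 0.0187). Of these 7 calls, the one for myeloid markers alone passed within deciles of peak signal by the Cochran-Mantel-Haenszel test. There the odds ratios were 0.357 (main 0.12) for HOX active, 0.259 (main 0.16) for neuronal active, 0.467 (main 0.243) for T cell silent, 0.53 (main 0.229) for fibroblast silent, 0.235 (main 0.115) for hepatocyte silent, 1.01 (main 0.362) for HOX silent and 0.0763 (main 0.0529) for myeloid silent regions. Calls also missed the threshold, with odds ratios still below 1, for fibroblast silent regions (0.25 with 500 bp, 0.358 with 2 kb), hepatocyte silent regions (0.376 with 500 bp, 0.152 with regions of at least 100 bp, 0.126 at the more accessible gene end alone, 0.0995 within deciles of gene length), HOX silent regions (0.398 with 500 bp, 0.436 within deciles of gene length) and neuronal active regions (0.267 with regions of at least 100 bp). Active regions at myeloid markers (6 of 14; Fisher's exact test, adjusted p = 0.835), T cell markers (8 of 23; Fisher's exact test, adjusted p = 0.278), fibroblast and mesenchymal markers (4 of 16; Fisher's exact test, adjusted p = 0.128) and hepatocyte markers (1 of 7; Fisher's exact test, adjusted p = 0.191) did not pass, nor did silent regions at neuronal markers (6 of 15; Fisher's exact test, adjusted p = 0.263).

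**Figure D4:**
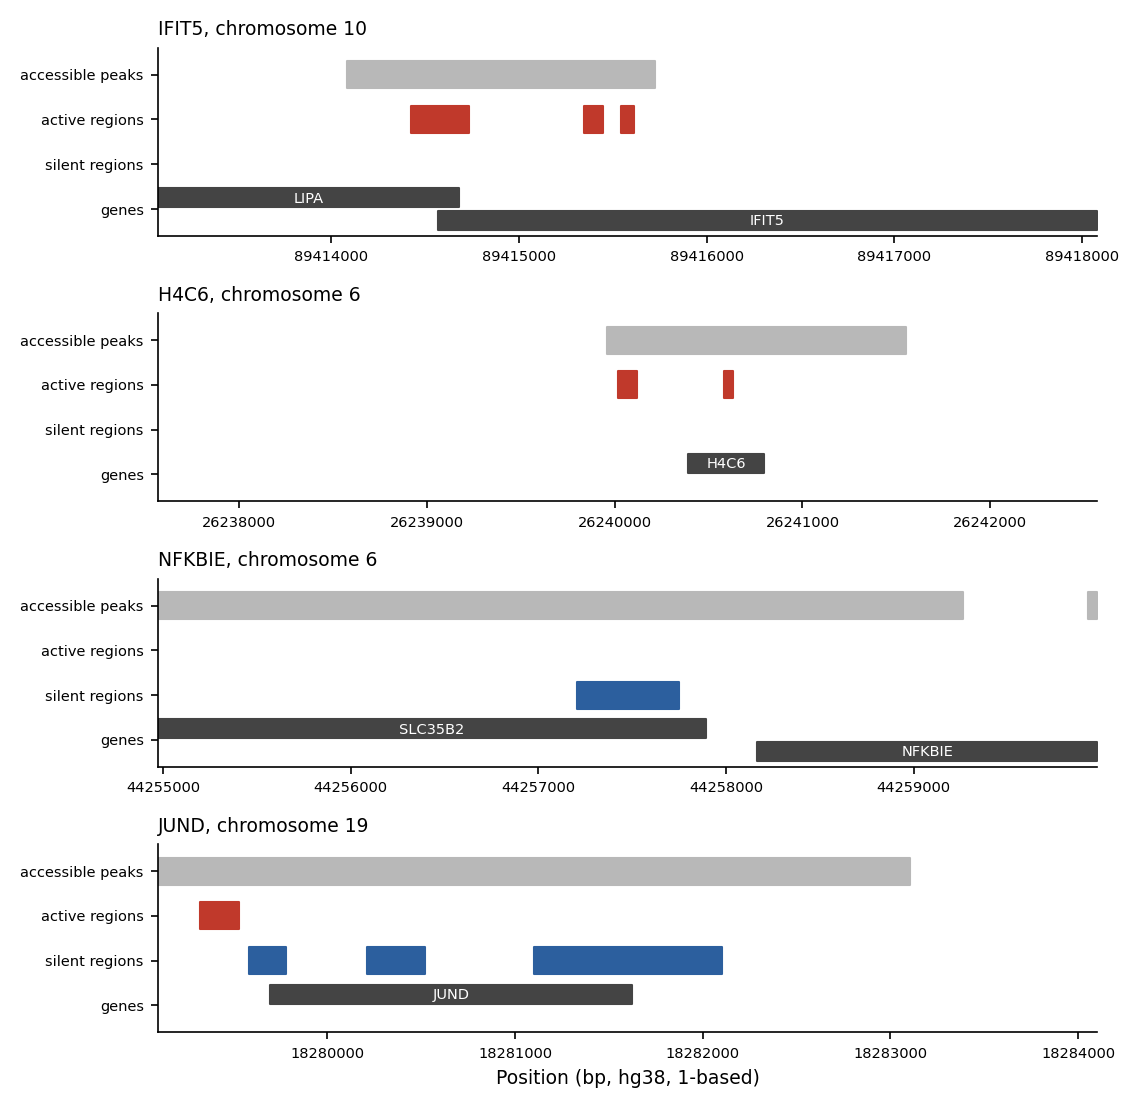
Maps of 5 kb around the region that holds the strongest called bin at 4 genes that ranked first in their list, with accessible peaks (grey), active regions (red), silent regions (blue) and protein-coding genes (dark bars on alternate levels), in bp of hg38. The IFIT5 and H4C6 windows hold active regions only, the NFKBIE window a silent region only, and the JUND window 1 active and 3 silent regions; a further active region at JUND and a further silent region at NFKBIE lie outside the drawn windows.

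Peaks with calls were stronger than peaks without. The median signal was 4210 for peaks with active calls only, 5276 for silent calls only, 15290 for both and 1189 for neither. The difference from peaks with neither was 3020 (95% block bootstrap interval 2921 to 3144) for active calls and 4087 (3812 to 4326) for silent calls, and each was above 0 on 23 of 23 chromosomes (two-sided sign-flip permutation test, p = 1e-05, the smallest possible). Silent-only peaks exceeded active-only peaks by 1066 (756 to 1304), on 22 of 23 chromosomes (two-sided sign-flip permutation test, p = 1e-05). The signal grows with peak length, and the median widths were 765 bp (active only), 922 bp (silent only), 1728 bp (both) and 381 bp (neither). Divided by length, the median signals were 5.46, 5.97, 8.72 and 3.19, the same order with smaller relative gaps. Peak strength can also set how well a call can be made. These differences therefore do not show that stronger peaks are more often active or silent.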

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

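The test of the gene-end position over deciles of signal per bp and length was chosen after related values had been seen. The tests on separate parts of a peak, on the more accessible gene end, on gene length and on rotations along the gene order were added after the data were examined. Each pattern below was found and tested on the same data, and no biological explanation was tested, since the series has 1 cell line and 1 condition.

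The peak list held 8 peaks on contigs outside chromosomes 1 to 22 and X, which no comparison used. None of their bins was called active or silent.

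Silent regions lay nearer gene ends than active regions. Over deciles of peak signal per bp crossed with deciles of peak length, the odds ratio for a gene-end position, active against silent, was 0.344 (95% interval 0.32 to 0.371), which argues against peak depth and length as the whole cause. It was below 1 on 23 of 23 chromosomes, which argues against a few chromosomes. With windows at the more accessible end of each gene alone it was 0.322 (0.3 to 0.346). This setting could change little, since 10526 of the 13686 genes with a peak had it at 1 end only. The kept window can also cover a neighbouring gene, and the more accessible end need not be the 5' end. Whether 3' ends and neighbouring genes play a part therefore stays open. Base composition, which differs at promoters and could change cloning or amplification, stays open because no genome sequence was used here.

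Active and silent calls shared a peak less often than peaks of like length would give. A bin holds at most 1 call. Calls on opposite sides of the peak midpoint, which do not compete directly for a bin, had an odds ratio of 0.525 (95% interval 0.501 to 0.548). Neighbouring bins can share cloned fragments. Calls at opposite ends of the 3536 peaks of at least 2 kb, 1 kb or more apart, had an odds ratio of 0.8003 (0.693 to 0.923). The value lay nearer to 1 in these more distant parts, so shared bins and fragments may account for part of the pattern. Whether they account for all of it stays open. Silent calls in 1 part may go with silent calls in the other, which take bins from active calls there. These comparisons also held neither peak signal nor distance to gene ends fixed. Over deciles of length crossed with deciles of signal per bp, the odds ratio for sharing a peak was 0.259 (0.242 to 0.274), which argues against peak depth as the whole cause.

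Interferon-stimulated and replication-dependent histone genes nearly all held active regions. The odds ratios were 37.7 and 52.5, with windows of 500 bp 8.92 and 34.3, and with regions of at least 100 bp 14.4 and 20.6. Within deciles of peak signal they were 99.8 and 44.2, and within deciles of gene length 34.0 and 54.2, which argues against stronger peaks and short genes as the whole cause. Many histone genes stand in clusters and share peaks. The exact p over all rotations of the list along the gene order was 7.31e-05 for both lists, the smallest possible. Rotation keeps which listed genes are neighbours, but not how often neighbours share a region, as H2AC17 and H2BC17 did. It therefore cannot decide how far shared regions raise the count of histone genes. A response of the cells to the plasmid DNA itself stays open for the interferon-stimulated genes, since all reporter libraries came from cells that held plasmids.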

How the results depend on the processing

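No paired analysis was possible because no value per library was analysed here; for the same reason, leaving out each replicate could not be run. Also not run were 1 start site per gene (no strand), a stricter bin threshold (bins carry no p), and all settings for base composition and motifs (no genome sequence). Requiring 0.5 of a region to lie in the peak changed nothing, because no region leaves its peak, so it says nothing about stability. The gene-end odds ratio stayed below 1, from 0.272 to 0.354, and co-occurrence over strata from 0.252 to 0.8003; without strata co-occurrence turned to 1.92, since longer peaks hold more of both calls. All peak strength differences kept their sign and interval away from 0. Called shares rise with peak signal, so a missing call in a weak peak does not show a lack of activity; the smallest active bin value was 0.827 in the lowest decile of signal per bp and 0.142 in the highest.

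The share of peaks near gene ends was 10.6% with 500 bp, 18.4% with 2 kb, 22.2% above the median signal and 11.6% with the more accessible end alone. Regions of at least 100 bp numbered 15203 (active) and 13560 (silent). The gene-end minus other value within deciles of signal per bp was -0.00894 (active; -0.277 over all) and -0.21 (silent; -0.0469 over all). For active regions, the difference thus went largely with peak signal per bp. Why the other values in this paragraph moved was not tested.

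Of 21 list calls, 10 passed in all 7 settings: more active regions at histone, interferon-stimulated, ribosomal protein, oxidative phosphorylation and proteasome genes, and fewer silent regions at histone, interferon-stimulated, ribosomal protein, oxidative phosphorylation and myeloid genes. Among these, odds ratios moved by over 1.5 times for active calls at histone (52.5 to 20.6 with 100 bp), interferon-stimulated (37.7 to 8.92 with 500 bp and 99.8 over peak signal), ribosomal protein (6.83 to 3.67 with 1 end) and oxidative phosphorylation genes (5.43 to 3.42 with 100 bp), and for silent calls at histone (0.0743 to 0.0182 with 100 bp) and myeloid genes (0.0529 to 0.219 with 2 kb). With 2 kb, 10 lists had more active genes (main 7), because B cell (adjusted p = 0.0133, Fisher's exact test), NF-kB (adjusted p = 0.0355, Fisher's exact test) and immediate-early genes (adjusted p = 0.0463, Fisher's exact test) passed as well. With 500 bp, 1 list had more silent genes (main 2) and 6 fewer (main 10). Within deciles of peak signal, 0 lists had fewer active genes (main 2), 0 more silent and 6 fewer silent. With regions of at least 100 bp, 1 list had fewer active genes. Directions turned, in lists and settings that did not pass unless named: NF-kB silent (1.19 with 2 kb, 1.27 with 100 bp, 1.01 over gene length), immediate-early active (0.739 over peak signal, 0.936 with 1 end), DNA replication active (1.07 with 2 kb, 1.09 with 100 bp), and over peak signal cholesterol active (0.85), unfolded protein response silent (0.792), T cell active (1.58), myeloid active (1.55) and HOX silent (1.01), the last of which had passed in the main test. The cause was not tested.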

Other observations

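All tests in this part were chosen after the data were examined. Gene families, defined by a shared symbol prefix and at least 10 accessible genes, were compared with all other accessible genes (159 families, 318 Fisher's exact tests, Benjamini-Hochberg adjustment). Of these tests 23 passed, 22 of them also by rotation along the gene order. Unlike the lists, families were not tested within deciles of peak signal, so peak strength was not taken into account. Among mitochondrial ribosomal protein genes, an active region was present at 38 of 46 MRPL genes (82.6%; Fisher's exact test, adjusted p = 0.000324) and at 24 of 27 MRPS genes (88.9%; Fisher's exact test, adjusted p = 0.000956), and a silent region at 30.4% and 25.9%. The RPL prefix passed for more active regions (45 of 50, Fisher's exact test, adjusted p = 4.31e-07) and for fewer silent regions (34%, Fisher's exact test, adjusted p = 0.00902). The RPS prefix passed for neither, with 27 of 41 genes active (Fisher's exact test, adjusted p = 0.199) and 51.2% silent (Fisher's exact test, adjusted p = 0.668). Of the RPS genes 28 of 41 are in a fixed list, against 42 of 50 RPL genes. The RPS share therefore need not describe ribosomal protein genes alone, and the difference between the prefixes was not tested. Active regions were also frequent at genes of RNA-binding motif proteins (RBM, 30 of 36), DEAD-box helicases (DDX, 25 of 30) and mitochondrial inner membrane translocases (TIMM, 13 of 14). ZNF genes, which encode zinc finger proteins, had active regions at 61.1% of 427 genes and silent regions at 48.7%, against 48.6% and 59.6% of other genes. Silent regions were frequent at ubiquitin-specific proteases (USP, 37 of 44; Fisher's exact test, adjusted p = 0.0112) and sorting nexins (SNX, 25 of 29; Fisher's exact test, adjusted p = 0.031). All 12 accessible PCDHGA protocadherin genes, which stand in 1 cluster, had an active region and none a silent one. Windows of neighbouring genes can overlap, so 1 region can count for several genes, and the 12 may not be separate observations. By rotation (exact over all rotations), the active test passed narrowly (adjusted p = 0.0495) and the silent test did not (adjusted p = 0.062). Olfactory receptor genes (OR) had fewer calls of both kinds than other genes, a silent region at none of 15 (Fisher's exact test, adjusted p = 0.000151) and an active region at 1 of 15 (Fisher's exact test, adjusted p = 0.015).

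Genes not annotated as protein-coding, taken where no protein-coding gene end lay within 2 kb, were counted by type, with no test between types. Of 200 accessible tRNA genes, 53.0% (95% Wilson interval 46.1 to 59.8) had a silent region and 80 of the 200 (33.5 to 46.9%) an active one. Of 3216 accessible lncRNA genes, 20.4% (19.0 to 21.8) had a silent and 27.9% (26.4 to 29.5) an active region. Of 107 accessible snoRNA genes, 7.48% (3.84 to 14.1) had a silent and 23.4% (16.4 to 32.2) an active region. Silent and active regions were present at 18 and 17 of 40 snRNA, 49 and 67 of 277 miRNA, 2 and 12 of 50 J segment and 6 and 5 of 44 V segment genes. The intervals treat genes as independent.

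Of the 87986 peaks farther than 1 kb from a gene end, those within 50 kb of listed genes were compared with the rest over deciles of peak length, where a call needed both an adjusted p under 0.05 (Cochran-Mantel-Haenszel test, Benjamini-Hochberg over 38 tests) and a block bootstrap interval without 1. By both criteria 4 tests passed, all for silent calls. The odds ratio was 2.60 (95% block bootstrap interval 1.57 to 3.70) near HOX and developmental regulators, 1.98 (1.2 to 3.02) near neuronal markers, 1.52 (1.05 to 2.09) near ribosomal protein genes and 0.644 (0.501 to 0.792) near genes of B cell identity. Silent calls near replication-dependent histones (13 of 76 peaks, odds ratio 2.5) met the first criterion alone, as the interval was 0 to 2.68. Near HOX and developmental regulators, 26 of 161 such peaks had a silent call. Peaks were not compared within deciles of peak signal here, so peak strength was not taken into account.

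Across 23 chromosomes, the share of silent bins went with the share of peaks near gene ends (Pearson r = 0.502, permutation p = 0.0127; Spearman rho = 0.289, permutation p = 0.182), as did the share of active bins (Pearson r = 0.584, permutation p = 0.008; Spearman rho = 0.405, permutation p = 0.0564). The Benjamini-Hochberg adjusted p over both Pearson tests was 0.0127 for each. Without chromosomes 19 and 17, Pearson's r was 0.137 (permutation p = 0.553) for silent and 0.288 (permutation p = 0.209) for active bins, so both relations rest on those chromosomes.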
